A study of Arachis hypogaea with 15 samples.

How the data were processed

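Steady-state transcript levels were measured by RNA sequencing in cultivated peanut (Arachis hypogaea), an allotetraploid legume with an A and a B subgenome of similar gene content. Per the labels' protocols, plants were 40 days old and were kept in a growth chamber with a 16 h day at 22 °C and 70% relative humidity. Total RNA was reverse transcribed with random primers and sequenced on an Illumina instrument. The 15 libraries form 5 groups of 3, which the series' design text calls biological replicates. The 4 wild-type groups are the shoot apex, the petiole, the terminal leaflet and the lateral leaflet, and the 1 mutant group is the shoot apex of a plant with an altered number of leaflets. No gene is named for the mutation in the labels. The columns of the leaflets carry other abbreviations than the library titles, and were matched through the tissue that each title's label gives.

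The authors deposited FPKM values, per the file headers, for 59878 genes, printed to 2 decimals. Each library's column is present 2 times with identical values and was read once. The aligner, the quantification tool and the depth used for the FPKM are not given in the sources used here. The submitters' processing notes name TAIR10, an Arabidopsis build, while the gene identifiers and chromosomes in the file are those of the peanut Tifrunner genome, first assembly and annotation, and coordinates are given as the file gives them. Product names come from the same file and were blank for 868 genes. The authors also deposited log2 ratios, p-values and q-values of pairwise group comparisons, per the file headers, with the test not given in the sources used here. These were used only for the side-by-side counts credited to the authors' deposited table. A gene table of another peanut assembly was not used here.

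The fixed design named a count test, with a second choice for normalized values. Because the file holds FPKM, the second choice was used. Genes at 1 FPKM or more in at least 3 libraries were kept (39031 of 59878), values were transformed as log2(FPKM + 1), and 1 linear model with a mean per group was fitted over all 15 libraries with limma 3.58.1 (trend and robust empirical Bayes) in R 4.3.3. Every fold change is therefore on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were the mutant against the wild-type apex, the terminal against the lateral leaflet, the wild-type apex against the mean of the leaflets, the petiole against the mean of the leaflets, and the wild-type apex against the petiole. Of these, 4 were treated as main comparisons and the last was described by counts and gene lists only. Tables were read with data.table (version 1.17.8) and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

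The 29 gene lists were fixed as patterns on the product names before the data were examined, as were the test, the named-gene rule and most alternatives. They cover class I KNOX, BELL, organ boundary, LEAFY and UNUSUAL FLORAL ORGANS (LFY-UFO), leaf polarity, PALM1-like zinc finger, CIN-type TCP, GRF-GIF, stem cell and floral genes. The hormone and stress lists are cytokinin, gibberellin, auxin, abscisic acid and drought, jasmonate and wounding, heat shock and defence. The others are circadian clock, photosynthesis, cell division, histones, ribosomal proteins, secondary wall and lignin, cuticle and epidermis, stomatal lineage, phloem, flavonoid, seed storage, and root and nodule genes. Lists of at least 5 tested genes (28 of the 29) were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 140 tests, which are the 28 lists in the 5 comparisons. The same test was run with an estimated correlation, and limma's fry was run as an alternative that asks only whether a list's genes moved one way and does not compare them with other genes. The pattern for CIN-type TCP genes also caught 33 products of other transcription factor families, so the 8 TCP products were tested apart as an alternative added after the data were seen. The cytokinin pattern also caught APRR products of the circadian clock, which are in the circadian clock list as well.

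A fixed rule gave a set of genes to name, not all of which are in the text. Some genes named in the text or drawn in the figures were chosen outside this rule, after the data were seen. In each main comparison the rule's genes are the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 FPKM in the higher group, no overlap between the libraries compared and a named product, with 1 gene per product name. To these were added the member with the smallest p of each development list, called or not, and of each other list that passed camera. Homeologous and tandem copies of near-identical sequence can exchange reads in short-read quantification, so values of single copies are uncertain where a close copy exists. Among the tested genes, 970 sets of entries (1960 genes) share chromosome, start and the values of every library, and were taken as repeated entries of a gene.

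Neighbouring genes that moved together were searched for on the 20 chromosomes, after the data were seen. Log2 changes were centred on their median and limited to 2 either way. The best run of tested genes per chromosome and direction was then taken after 0.5 was subtracted per gene, and its score was compared with the highest score in 1000 permutations of the gene order. Runs of at least 20 tested genes with a score above every permuted score were carried on as segments.

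FPKM sums ranged from 573000 to 620600 per library and 34260 to 35450 genes reached 1 FPKM. Read counts were not used here. The most frequent product of low values and transcript length, taken as the step of a single fragment, gave an estimated 16.7 to 17.8 M fragments per library. By that estimate the median variance between replicates was 1.3 to 1.45 times the sampling variance for genes of 20 to 50 fragments, and 5.19 to 12.8 times for genes above 5000 fragments. Deviations from the group means were not shared by libraries with the same replicate number, so no block was used.

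The pipeline was tested on simulated libraries drawn from the real genes' mean levels and fitted variances and 200 genes changed 1.5-, 2- or 4-fold. For the mutant comparison (37118 genes tested) it recovered 61.2%, 77.6% and 98.5% of these genes, with 10 false calls (5.95% of the calls). Recovery of 2-fold changes was 85.1% for the leaflet comparison, 82.1% for apex against leaflets, 91% for petiole against leaflets and 86.6% for apex against petiole, and no call was in the wrong direction. A planted list passed camera and 0 of the other 27 lists did, and the scan found 98 of 100 planted neighbours on chromosome 10 and no run on another chromosome. The simulated genes were drawn independently of each other, so this does not test false list calls among correlated genes. Alternatives covered scaling, the expression filter, the pseudocount, the libraries in the fit, a replicate block, a 2-fold minimum and each library left out in turn.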

Results

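The data describe the transcriptome of 4 peanut tissues in 5 groups, sampled to follow the development of the compound leaf. Peanut leaves carry paired leaflets on a petiole and rachis. The wild-type shoot apex, petiole, terminal leaflet and lateral leaflet were each represented by 3 libraries, and the shoot apex of a mutant with altered leaflet number by another 3. Levels are given as FPKM with the standard deviation over the libraries of a group. Library depth, estimated from the steps between low values, was 16.7 to 17.8 M fragments. Replicates of a group correlated at 0.988 to 0.99 across genes, which are not independent replicates. The first principal component held 75.2% of the variance between libraries and the next held 11.9%. All adjusted p-values of single genes below are from limma, and those of lists are from limma's camera over 140 tests. The latter use the preset correlation unless stated, and the smallest of them were far larger with an estimated correlation.

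The comparison of the mutant with the wild-type shoot apex concerns the tissue that initiates leaves. Differences in plant background or harvest time cannot be told apart here from an effect of the mutation. Class I KNOX genes, homeobox regulators that keep meristem cells undifferentiated and act in compound leaf primordia, were higher in the mutant apex. The knotted-1-like gene arahy.0VJ2KM.1 (chromosome 6, 111953664 to 111965283) stood at 54.3 ± 3.37 FPKM in the mutant and 25.4 ± 1.05 in wild type (n = 3 each), a log2 change of 1.06 (adjusted p = 8.26e-08). TCP genes of the CIN type, which end cell proliferation in growing leaves, were lower. The TCP3-like gene arahy.7QL5S6.1 (chromosome 3, 28296178 to 28298188) stood at 8.42 ± 0.0569 FPKM in the mutant and 23.9 ± 0.833 in wild type (n = 3 each), a log2 change of -1.40 (adjusted p = 1.68e-11). Genes of sieve element occlusion proteins, which form plugs in phloem sieve tubes, were also higher. The gene arahy.FIX3WY.1 (SIEVE ELEMENT OCCLUSION B) rose from 4.15 ± 0.14 to 17.5 ± 0.614 FPKM (n = 3 each, log2 change 1.84).

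Of 18 tested class I KNOX genes, 11 were higher and 0 lower (14 and 0 adjusted over the list alone). The list's median log2 change was 0.46 (camera adjusted p = 5.48e-05). A gene of the same product name on chromosome 16, arahy.A8JEVC.1, rose from 49 ± 2.27 to 69.1 ± 0.826 FPKM (n = 3 each, adjusted p = 1.12e-05). The SBH1-like gene arahy.EP4LC1.1 rose from 15.6 ± 1.38 to 25.7 ± 0.382 (n = 3 each, adjusted p = 2.32e-06). The list fixed for CIN-type TCP genes held 41 tested members, of which 17 were lower and 5 higher (17 and 7 adjusted over the list alone; camera adjusted p = 0.000221). Of these members, 33 are products of other families. The member with the smallest p was such a product, a probable WRKY transcription factor gene on chromosome 5 (start 115464468). It stood at 0.02 ± 0.0173 FPKM in the mutant and 11.2 ± 0.301 in wild type (n = 3 each). The 8 TCP products themselves were lower in 8 of 8 cases, overall and adjusted over the list alone, with log2 changes from -1.40 to -0.35 and a camera adjusted p of 3.53e-11 over the 5 comparisons. The selection of these 8 was made after their values were seen. Growth-regulating factors and their cofactors (GRF-GIF), which promote leaf cell proliferation, were lower in 10 and higher in 1 of 30 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00618). Among these arahy.FF6C67.1 (growth-regulating factor 9) fell from 14.4 ± 0.666 to 9.46 ± 0.573 FPKM (n = 3 each).

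**Figure D1:**
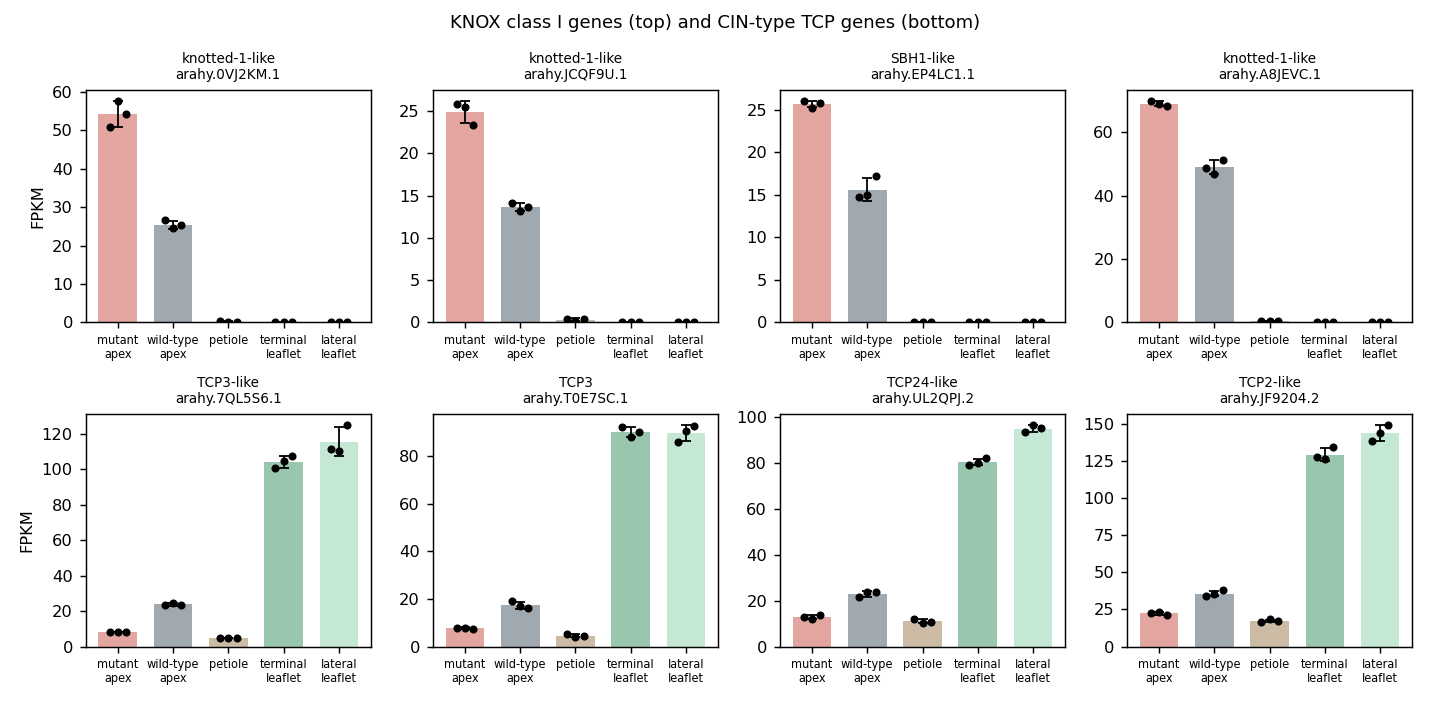
FPKM (vertical axes, linear from 0) of 4 class I KNOX genes (top) and 4 CIN-type TCP genes (bottom) in the 5 groups; bars are group means, points the 3 libraries and error bars the SD. The KNOX genes shown are higher in the mutant than in the wild-type apex and near 0 in leaflets (arahy.0VJ2KM.1: 54.3 against 25.4 FPKM), and the TCP genes are lower in the mutant apex (arahy.7QL5S6.1: 8.42 against 23.9 FPKM).

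Phloem genes were higher in 27 and lower in 4 of 35 (27 and 5 adjusted over the list alone), with a median log2 change of 0.89 (camera adjusted p = 3.05e-09). Among them 27 are sieve element occlusion products, 7 each on chromosomes 9 and 19, and of these 22 were higher and 4 lower. Near-identical neighbours among them may exchange reads. Cytokinin genes were higher in 42 and lower in 5 of 90 (45 and 6 adjusted over the list alone; camera adjusted p = 0.00255). These counts include APRR genes of the circadian clock, caught by the list's pattern, some of them called higher and arahy.V64N20.2 (APRR5) lower. The response regulator arahy.FQ5ZUR.1 (ORR9-like), whose type dampens cytokinin signalling, rose from 6.25 ± 0.169 to 12.3 ± 0.878 FPKM (n = 3 each). Ribosomal proteins were higher in 208 and lower in 10 of 346 (222 and 11 adjusted over the list alone; camera adjusted p = 3.63e-11). For histones the counts were 34 and 2 of 45 (35 and 2 adjusted over the list alone; 2.32e-07), and for cell division genes 79 and 9 of 183 (82 and 9 adjusted over the list alone; 0.000504). The linker histone arahy.1UPR0X.1 went the other way, from 143.5 ± 2.68 to 94 ± 2.79 FPKM (n = 3 each). With an estimated correlation the camera adjusted p was 0.0214 for ribosomal proteins and 0.0414 for histones. Photosynthesis genes were higher in 52 and lower in 14 of 116 (56 and 14 adjusted over the list alone; camera adjusted p = 0.0182), and this call was lost with an adjusted p = 0.265 with an estimated correlation.

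Heat shock genes were lower in 41 and higher in 16 of 86 (42 and 18 adjusted over the list alone; camera adjusted p = 3.25e-08). The chaperone gene arahy.3X8NRX.1 (heat shock cognate 70 kDa protein 2-like) fell from 48.8 ± 0.89 to 7.48 ± 0.278 FPKM (n = 3 each). Abscisic acid and drought genes were lower in 18 and higher in 7 of 59 (19 and 9 adjusted over the list alone; 0.000634). The gene arahy.PIX3LG.1 (late embryogenesis abundant protein 2) fell from 13.6 ± 0.944 to 0.88 ± 0.0781 FPKM (n = 3 each). Jasmonate and wounding genes were lower in 23 and higher in 14 of 79 (23 and 15 adjusted over the list alone; 0.00255). The lipoxygenase gene arahy.V9UCIZ.1, for an enzyme of oxylipin synthesis, fell from 669.7 ± 19.2 to 207.4 ± 1.66 FPKM (n = 3 each). Cuticle and epidermis genes were lower in 72 and higher in 38 (74 and 41 adjusted over the list alone; 0.00021). The lipid-transfer protein gene arahy.PX59SB.1 fell from 14 ± 1.57 to 1.34 ± 0.221 FPKM (n = 3 each). Root and nodule genes were lower in 8 and higher in 5 of 30 (the same numbers adjusted over the list alone; 0.0197), a call lost with an adjusted p = 0.0634 with an estimated correlation. Circadian clock genes were lower in 16 and higher in 10 of 44 (16 and 11 adjusted over the list alone; 0.000944). That list's median was 0.04 while its mean was -0.39 and its test pointed down, and the median turned to -0.01 under quantile normalization.

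The other lists did not pass camera in this comparison. Higher and lower counts were 2 and 0 of 6 for LFY-UFO (adjusted p = 0.441), 7 and 1 of 23 for stem cell genes (0.441) and 17 and 6 of 63 for floral genes (0.661). They were 15 and 9 of 54 for gibberellin (0.696), 73 and 41 of 242 for auxin (0.749), 170 and 47 of 576 for defence (0.252), 2 and 4 of 36 for the stomatal lineage (0.406) and 0 and 2 of 5 for seed storage (0.0989). Under quantile normalization lower calls came to outnumber higher ones in 5 lists: BELL (6 and 6 of 27, then 5 and 8; adjusted p = 0.234), organ boundary (6 and 2 of 30, then 5 and 6; adjusted p = 0.989), leaf polarity (15 and 14 of 57, then 13 and 15; 0.348), secondary wall and lignin (38 and 35 of 196, then 28 and 44; 0.156, and 0.0394 pointing down with an estimated correlation) and flavonoid genes (20 and 20 of 91, then 17 and 25; 0.285). Among leading members, arahy.B9XEKF.1 (CUP-SHAPED COTYLEDON 2-like, a boundary factor) stood at 10.2 ± 0.446 against 7.4 ± 0.257 FPKM (n = 3 each, adjusted p = 0.000566), and arahy.P6GRAY.1 (UNIFOLIATA-like, the LEAFY ortholog that acts in legume compound leaves) at 3.25 ± 0.0945 against 2.51 ± 0.285 (n = 3 each, adjusted p = 0.0105). With a pseudocount of 0.1 these changes had adjusted p = 0.275 and 0.261, and the call of arahy.P6GRAY.1 was also lost without replicate 3 of the wild-type apex (0.051). The PALM1-like list held 2 tested entries of 1 gene, the SUPERMAN gene arahy.FUQZ4V.1, which was lower in the mutant apex (0.647 ± 0.0351 against 1.96 ± 0.152 FPKM, n = 3 each, adjusted p = 2.17e-06).

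The largest falls were concentrated in neighbouring genes. On chromosome 5, from 113789406 to 115884540, the scan found 134 tested genes with a median log2 change of -2.01, of which 129 were lower, and the run reached the last listed gene of the chromosome. Its score was 146.3, against at most 5.41 in 1000 permutations. Of 66 genes there at 5 FPKM or more in the wild-type apex, the median mutant level was 0.5% of wild type, with quartiles of 0.0491% and 9.3%. Among these genes 44 were below 5% and 15 were listed at 0, while 12 were above 20% and the highest stood at 108.4%. Of the 66, 64 reached 1 FPKM in the petiole and both leaflets. The aquaporin gene arahy.7IIA7U.1 (PIP2-1) fell from 75.6 ± 5.43 to 0.183 ± 0.0153 FPKM (n = 3 each), the cellulose synthase-like gene arahy.82KWKE.2 from 379.5 ± 3.34 to 0.0433 ± 0.0321, and the chlorophyll-binding protein gene arahy.BTM1YE.1 from 78.2 ± 1.81 to 0.32 ± 0.306. The splicing-related gene arahy.XJQY2Y.1 (LSM3A) and the clock gene arahy.AF3FG0.1 (GIGANTEA-like) were listed at 0 in all 3 mutant libraries, with wild-type means of 46.9 ± 7.62 and 13.2 ± 0.507 FPKM (n = 3). At the border, arahy.SB31NP.1 stood at 54.3 against 51.7 FPKM and its neighbour arahy.A992JM.1 (SGT1 homolog) at 1.03 against 25.6. On chromosome 17, from 628310 to 3239506, 170 of 189 tested genes were higher (score 44.2, at most 3.49 in 1000 permutations). The 90 genes at 5 FPKM or more in wild type stood at a median of 2.02 times the wild-type level, with quartiles of 176.6% and 216.4%. Without the 323 genes of these segments, 13505 genes were called in the mutant comparison and no list changed its call.

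**Figure D2:**
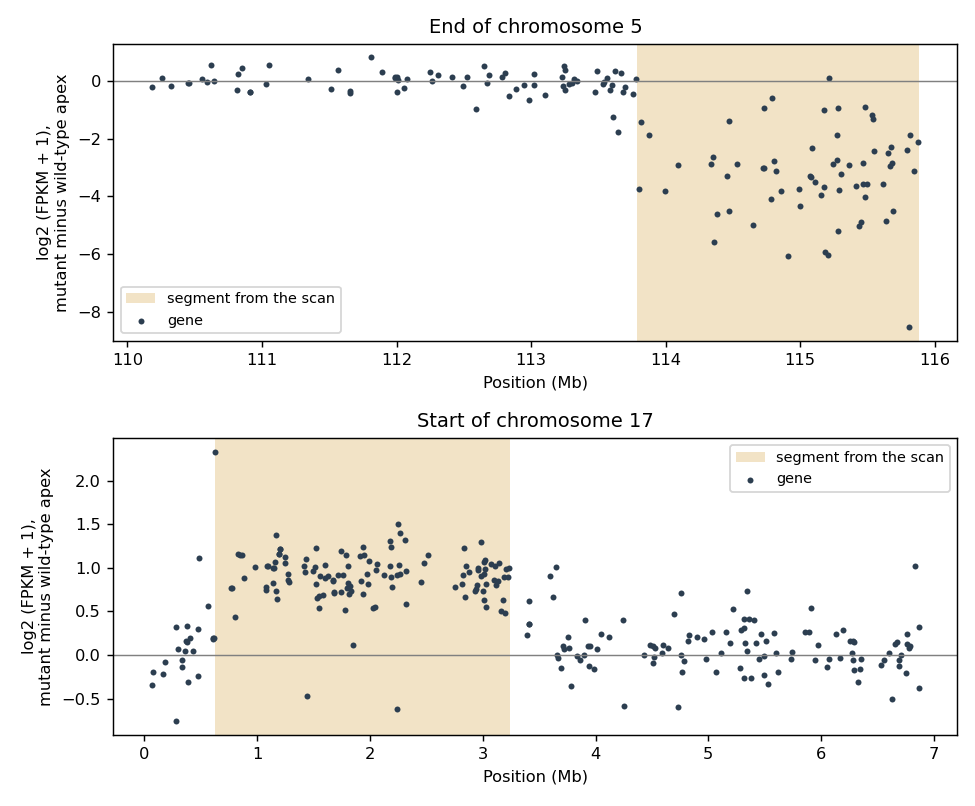
Log2 (FPKM + 1) change of single genes, mutant minus wild-type apex (vertical axis), against position in megabases (horizontal axis) near the end of chromosome 5 (top) and the start of chromosome 17 (bottom), for genes at 5 FPKM or more in the mutant or the wild-type apex; shading marks the segments found by the scan. Of the genes at 5 FPKM or more in the wild-type apex, those in the shaded part of chromosome 5 stand at a median of 0.5% of wild type. Those in that of chromosome 17 stand at a median of 2.02 times wild type.

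Outside the segments, single genes rose or fell far. The vacuolar-processing enzyme gene arahy.D4D0YI.1, a protease of vacuolar protein maturation, rose from 3.76 ± 0.278 to 23.5 ± 1.24 FPKM (n = 3 each, log2 change 2.36, adjusted p = 5.62e-12). The gene arahy.CV46MP.1 (bHLH162-like) rose from 8.79 ± 0.732 to 35.7 ± 1.6 FPKM (n = 3 each). The seed maturation protein gene arahy.6M6V4C.1 fell from 69.4 ± 2.34 to 0.0133 ± 0.0231 FPKM (n = 3 each), and it was at 0.0533 or less in the petiole and leaflets. The gene of the U2af large subunit A on chromosome 12 (start 639455), a splicing factor, fell from 32.6 ± 1.58 to 0.02 ± 0.0173 FPKM (n = 3 each) and stood at 37.5 ± 1.03 in the petiole. On chromosome 9, neighbouring genes that include lectins moved both ways. All 5 tested genes from 119042797 to 119096231 were higher, among them arahy.QHFZ4L.1 (8.17 ± 1.64 to 38 ± 0.94 FPKM, n = 3 each). From 119177525 to 119405750, 6 of 9 were lower. Reads may be exchanged between such tandem copies.

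In all, 13876 of 39031 tested genes differed between the mutant and the wild-type apex, 9243 higher and 4633 lower. Under quantile normalization the split was 6889 higher and 6112 lower. A change of at least 2-fold was reached by 246 genes among the higher and 425 among the lower ones. The authors' deposited table gives 24992 of 50858 genes at q under 0.05 for this pair, 16259 higher and 8733 lower. Among the genes tested here it gives 22209. Of the 13816 genes called in both, 13814 had the same direction, but both sets of calls rest on the same libraries.

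The comparison of terminal with lateral leaflets sets leaflets of different position on the leaf against each other. The labels used here give no harvest hour, so an effect of position cannot be told apart from one of harvest time. Cuticle genes and LHY genes of the circadian clock were higher in terminal leaflets. The alkane hydroxylase gene arahy.U78CR3.1 (MAH1-like, an enzyme of wax synthesis; chromosome 13, start 9473869) stood at 40.4 ± 0.597 FPKM in terminal and 2.84 ± 0.101 in lateral leaflets (n = 3 each, log2 change 3.43, adjusted p = 2.19e-13). The clock gene arahy.J7VJ5I.2 (LHY, a morning-phased transcription factor; chromosome 12, start 6913004) stood at 29.6 ± 1.24 and 1.86 ± 0.134 FPKM (n = 3 each, log2 change 3.42, adjusted p = 2.53e-13). The Rubisco activase gene arahy.NME7KH.1 stood at 467.4 ± 4.88 and 131.3 ± 3.4 FPKM (n = 3 each, log2 change 1.82). Among the largest falls, the lectin CPL-like gene on chromosome 9 (start 119313160) stood at 10.7 ± 0.646 against 59.6 ± 1.22 FPKM (n = 3 each).

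Cuticle and epidermis genes were higher in 55 and lower in 23 (60 and 30 adjusted over the list alone; camera adjusted p = 9.8e-05), and 19 were at least 2-fold higher. Their median log2 change was 0, at 0.01 under quantile normalization and -0.01 under TPM rescaling, while the mean was 0.17. The wax regulator arahy.47HK44.1 (MYB94-like) stood at 34.9 ± 1.34 against 3.81 ± 0.617 FPKM and the myb-related gene arahy.GBQU8N.1 at 33.4 ± 1.26 against 3.78 ± 0.531 (n = 3 each). Photosynthesis genes were higher in 40 and lower in 4 of 116 (48 and 5 adjusted over the list alone; camera adjusted p = 9.52e-16). Ribosomal protein genes were higher in 160 and lower in 1 of 346, and in 202 and 3 adjusted over the list alone (camera adjusted p = 1.91e-33). For photosynthesis and ribosomal protein genes the camera adjusted p was 0.00403 and 0.00128 with an estimated correlation. Heat shock genes were higher in 29 and lower in 1 of 86 (32 and 5 adjusted over the list alone; 3.92e-11), and arahy.YQG5EZ.1 (heat shock protein 83) stood at 4.94 ± 0.405 against 1.1 ± 0.2 FPKM (n = 3 each).

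Histones were lower in terminal leaflets in 29 and higher in 0 of 45, and in 32 and 0 adjusted over the list alone. The camera adjusted p was 1.66e-13, and 0.00845 with an estimated correlation. Cell division genes were lower in 53 and higher in 2 of 183 (71 and 2 adjusted over the list alone; 4.55e-07). The phragmoplast kinesin gene arahy.S7JP6V.1 (KIN-12F) stood at 18.2 ± 0.204 against 24.5 ± 0.533 FPKM (n = 3 each, adjusted p = 4.27e-06). GRF-GIF genes were lower in 6 and higher in 0 of 30 (7 and 0 adjusted over the list alone; 0.00457). Jasmonate genes were lower in 27 and higher in 1 of 79 (31 and 1 adjusted over the list alone; 2.32e-07), with arahy.DQCW8K.1 (TIFY 10b, a repressor of jasmonate responses) at 10.2 ± 0.597 against 18.8 ± 0.593 FPKM (n = 3 each).

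Of the development lists other than GRF-GIF, no list passed camera between the leaflets. The organ boundary list had 3 higher and 0 lower of 30 (adjusted p = 0.0538), with arahy.1M0B45.1 (LIGHT-DEPENDENT SHORT HYPOCOTYLS 6) at 4.38 ± 0.686 against 0.993 ± 0.186 FPKM (n = 3 each). Leaf polarity had 1 higher and 8 lower of 57 (0.285), led by the gene of the KNOX repressor AS1, arahy.Z9PFJZ.1, at 42.2 ± 1.07 against 52.5 ± 3.02 FPKM (n = 3 each, adjusted p = 0.000294). The CIN TCP list had 0 higher and 4 lower of 41 (1 and 12 adjusted over the list alone; 0.126), and the stem cell list had 0 higher and 1 lower of 23 (0.47), arahy.2E2A40.1 (WUSCHEL-related homeobox 1-like). That call was lost when the fit held only these groups (adjusted p = 0.0596) and without any of 3 single libraries, which were terminal replicate 1 (0.0675), terminal replicate 3 (0.0624) and lateral replicate 1 (0.066). The secondary wall list had 22 higher and 15 lower of 196 (0.0725, and 0.0157 with an estimated correlation). Circadian clock genes were higher in 11, 8 of them at least 2-fold, and lower in 16 of 44, with a median of -0.08, a mean of 0.3 and an adjusted p of 0.551.

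**Figure D3:**
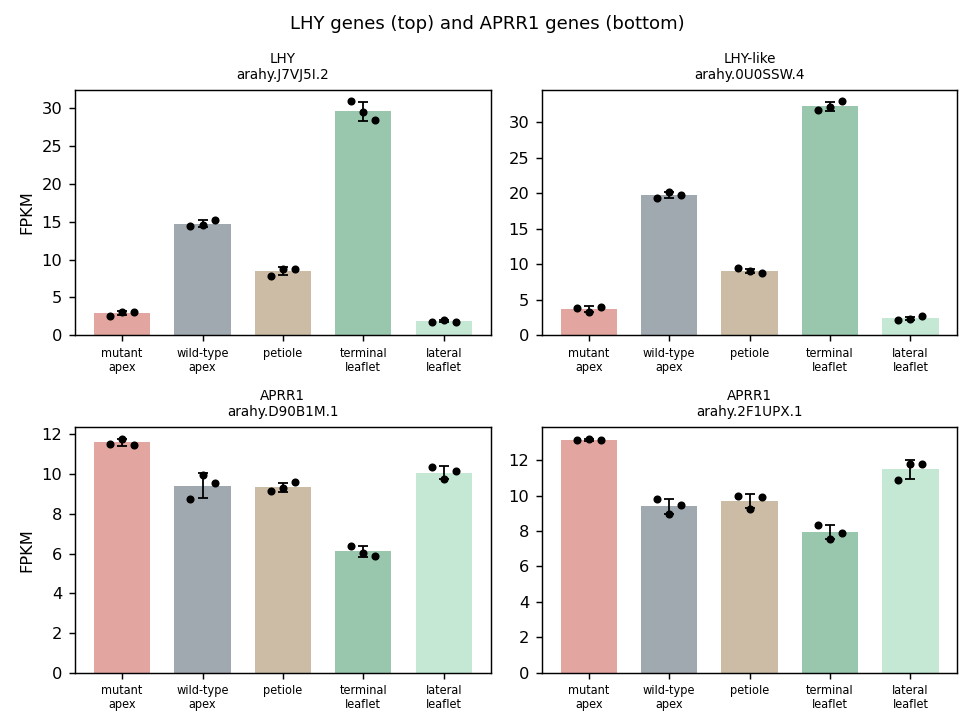
FPKM (vertical axes, linear from 0) of 2 LHY genes (top) and 2 APRR1 genes (bottom) in the 5 groups; bars are group means, points the 3 libraries and error bars the SD. The LHY genes are highest in terminal leaflets (arahy.J7VJ5I.2: 29.6 FPKM) and low in lateral leaflets and the mutant apex (1.86 and 2.9 FPKM), and the APRR1 genes are lowest in terminal leaflets.

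Between terminal and lateral leaflets 5106 genes differed, 2197 higher and 2909 lower, of which 198 and 48 were at least 2-fold apart. The authors' deposited table gives 14016 of 52535 genes at q under 0.05, 5493 higher and 8523 lower, and 12689 among the genes tested here. Of the 5050 genes called in both, 5049 had the same direction. No run of neighbouring genes scored above the permuted gene orders.

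The comparison of the wild-type shoot apex with the leaflets sets the tissue that initiates leaves against determinate blades. Class I KNOX and organ boundary genes were higher in the apex and photosynthesis genes lower. The KNOX gene arahy.A8JEVC.1 (chromosome 16, 150935770 to 150946553) stood at 49 ± 2.27 FPKM in the apex and 0.01 ± 0.0173 in both kinds of leaflet (n = 3 each, log2 change 5.63, adjusted p = 2.76e-19). The boundary gene arahy.0BJ33Y.1 (LIGHT-DEPENDENT SHORT HYPOCOTYLS 4-like) stood at 44.3 ± 1.05 in the apex against 0.313 ± 0.101 and 0.103 ± 0.0896 FPKM in terminal and lateral leaflets (n = 3 each). The photoprotection gene arahy.L9FPHH.2 (photosystem II 22 kDa protein) stood at 60.7 ± 1.13 in the apex against 627.9 ± 4.3 and 621.1 ± 15.6 FPKM (n = 3 each, log2 change -3.34).

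Class I KNOX genes were higher in 17 and lower in 0 of 18 (camera adjusted p = 9.74e-11), organ boundary genes in 29 and 0 of 30 (1.49e-13), LFY-UFO genes in 6 and 0 of 6 (0.000539) and GRF-GIF genes in 27 and 2 of 30 (1.75e-10). Adjusted over the list alone, these and the other counts of this comparison are the same unless given. Leaf polarity genes were higher in 40 and lower in 12 of 57 (40 and 13 adjusted over the list alone; 1.92e-05), with arahy.BZ1GLD.1 (YABBY 4) at 112.6 ± 6.27 against 5.16 ± 0.326 and 6.91 ± 1.1 FPKM (n = 3 each). Auxin genes were higher in 135 and lower in 58 of 242 (7.62e-06), and gibberellin genes in 33 and 15 of 54 (36 and 15 adjusted over the list alone; 0.00137), led by arahy.H2NMKM.3 (auxin response factor 6-like) and arahy.FJ610L.1 (gibberellin-regulated protein 4). Defence genes were higher in 315 and lower in 141 of 576 (5.42e-05), flavonoid genes in 55 and 26 of 91 (0.000167), phloem genes in 18 and 7 of 35 (0.00638) and heat shock genes in 50 and 23 of 86 (0.00141). The endochitinase-like gene arahy.62YWNW.1 stood at 241.3 ± 1.07 FPKM in the apex (n = 3) and was listed at 0 in terminal leaflets.

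Photosynthesis genes were lower in the apex in 99 and higher in 5 of 116 (camera adjusted p = 2.23e-17, and 0.00329 with an estimated correlation). Cell division genes were lower in 128 and higher in 24 of 183 (1.16e-05). The gene arahy.9JV7L8.1 (cyclin-D1-1) was higher, at 35.5 ± 1.66 against 7.14 ± 0.335 and 7.99 ± 0.0737 FPKM (n = 3 each). Histones were lower in 36 and higher in 5 of 45 (4.97e-06) and ribosomal proteins in 225 and 60 of 346 (9.8e-05), calls lost with adjusted p = 0.063 and 0.126 with an estimated correlation. Root and nodule genes were higher in 16 and lower in 9 of 30 (0.0212; adjusted p = 0.0645 with an estimated correlation), with arahy.JCK56G.1 (early nodulin-75) at 72.3 ± 2.13 FPKM in the apex and 0.397 ± 0.204 in terminal leaflets (n = 3 each). BELL (10 higher and 15 lower of 27, adjusted p = 0.948), CIN TCP (19 and 15 of 41, 0.545) and stem cell genes (13 and 5 of 23, 0.0557) did not pass. The TCP products were lower in 5 and higher in 0 of 8 (camera adjusted p = 0.00611), with arahy.N9U68C.1 (TCP13-like) at 1.2 ± 0.0854 in the apex against 68.8 ± 3.29 and 75.6 ± 1.42 FPKM (n = 3 each). The largest rises included arahy.QR8UZF.1 (proline-rich protein 36-like, 1784 ± 284 FPKM in the apex, n = 3) and arahy.80U1VQ.1 (lipid-transfer protein 2, 977.6 ± 54.5). The largest falls included arahy.WK2RNV.1 (7-ethoxycoumarin O-deethylase, 0.557 ± 0.123 FPKM in the apex against 438.1 ± 3.94 and 445.9 ± 10.4, n = 3 each), and arahy.VT6DM9.1 (BURP domain protein RD22-like) was listed at 0 in the apex. In all 31057 genes differed, 13764 higher and 17293 lower in the apex, and 3734 and 5483 were at least 2-fold apart. The balance depends on the scaling, with 15757 higher and 15264 lower under quantile normalization and 15352 and 15668 under TPM rescaling.

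The comparison of the petiole with the leaflets sets the leaf stalk against the blades. Lignin, flavonoid and boundary genes were higher in the petiole, and photosynthesis genes and the abaxial regulator YABBY 1 were lower. The methyltransferase gene arahy.I1E7E1.1 (caffeic acid 3-O-methyltransferase-like, an enzyme of lignin synthesis; chromosome 10, start 91153378) stood at 738.3 ± 15.5 FPKM in the petiole against 16 ± 0.0902 and 14.7 ± 0.609 in terminal and lateral leaflets (n = 3 each, log2 change 5.50, adjusted p = 4.4e-21). The gene arahy.AQ6B1J.1 (leucoanthocyanidin dioxygenase, an enzyme of anthocyanin synthesis) stood at 90 ± 3.31 against 0.397 ± 0.0987 and 0.65 ± 0.0529 FPKM (n = 3 each, log2 change 5.91). The gene arahy.GE3GK9.1 (axial regulator YABBY 1) stood at 0.367 ± 0.095 against 22.3 ± 1.06 and 20.8 ± 0.867 FPKM (n = 3 each, log2 change -4.04). The Rubisco small subunit gene arahy.FHUH7B.1 stood at 102.9 ± 0.797 against 1550 ± 118 and 1083 ± 16 FPKM (n = 3 each).

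Secondary wall and lignin genes were higher in 105 and lower in 57 of 196 (105 and 58 adjusted over the list alone; camera adjusted p = 1.18e-05). Flavonoid genes were higher in 54 and lower in 19 of 91 (1.98e-06), phloem genes in 22 and 9 of 35 (22 and 10 adjusted over the list alone; 0.000135) and auxin genes in 141 and 44 of 242 (141 and 45 adjusted over the list alone; 1.93e-08). Organ boundary genes were higher in 22 and lower in 1 of 30 (3.25e-08) and GRF-GIF genes in 22 and 5 of 30 (5.96e-06), with the same numbers adjusted over the list alone. KNOX genes were higher in 8 and lower in 0 of 18 with a median of 0 (0.0357), and the call was lost with an adjusted p = 0.058 with an estimated correlation and 0.193 under quantile normalization. Of the 8 higher genes, 3 were at least 2-fold higher, and the largest change was that of arahy.U5Q1QL.1 (knotted-1-like 1), at 18.5 ± 1.22 FPKM in the petiole, 6.04 ± 0.665 in the apex and 0.09 ± 0.0173 in terminal leaflets (n = 3 each). Leaf polarity genes were higher in 32 and lower in 21 of 57 (32 and 22 adjusted over the list alone; 0.0279, and 0.107 under quantile normalization), gibberellin genes in 34 and 15 of 54 (0.00115) and jasmonate genes in 38 and 24 of 79 (0.0234). Defence genes were higher in 233 and lower in 159 of 576 (233 and 156 adjusted over the list alone; 0.00839). Heat shock genes were higher in 44 and lower in 26 of 86 (44 and 27 adjusted over the list alone; 0.0194) and ribosomal proteins in 188 and 88 of 346 (1.18e-05), calls lost with adjusted p = 0.0634 and 0.0905 with an estimated correlation.

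Photosynthesis genes were lower in the petiole in 101 and higher in 3 of 116 (camera adjusted p = 6.07e-17, and 0.00344 with an estimated correlation). Cell division genes were lower in 134 and higher in 25 of 183, and in 134 and 26 adjusted over the list alone (camera adjusted p = 1.18e-05). Histones were lower in 35 and higher in 5 of 45 (camera adjusted p = 4.84e-07, and 0.0443 with an estimated correlation). The 8 TCP products were lower in 8 of 8 cases (6.92e-06), with arahy.7QL5S6.1 at 4.93 ± 0.135 against 104 ± 3.24 and 115.5 ± 8.06 FPKM (n = 3 each). The list with all 41 members had 15 higher and 18 lower (0.832). The wax gene arahy.SWLP8S.2 (ECERIFERUM 2-like) stood at 0.533 ± 0.085 against 109 ± 5.27 and 28.6 ± 0.727 FPKM (n = 3 each) within a cuticle list that did not pass (82 higher and 117 lower, 0.696). The largest rises were arahy.JI131A.1 and arahy.PGE1MU.1 (organ-specific proteins P4-like and P4), at 723.2 ± 5.64 and 789.3 ± 32 FPKM in the petiole against 1.44 ± 0.217 and 3.54 ± 0.767 in lateral leaflets (n = 3 each). They lie in runs of neighbouring genes on chromosome 3 (4399621 to 4701433, 14 of 19 tested genes higher) and chromosome 13 (7090615 to 7203072, 7 of 7 higher), both above every permuted score. In all 29200 genes differed, 12004 higher and 17196 lower in the petiole. Under quantile normalization the split was 15111 higher and 13656 lower, as that scaling moved the median log2 change of all tested genes from -0.11 to 0.025.

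The wild-type apex was also compared with the petiole. The apex was higher in class I KNOX genes (15 higher and 1 lower of 18, camera adjusted p = 5.33e-12), organ boundary genes (23 and 0 of 30, 2.19e-11), GRF-GIF genes (26 and 2 of 30, 1.48e-10), LFY-UFO genes (6 and 0 of 6, 7.46e-06) and stem cell genes (11 and 0 of 23, 0.00186). The KNOX gene that was lower in the apex was arahy.U5Q1QL.1. BELL (15 and 6 of 27, 0.0144), leaf polarity (22 and 13 of 57, 0.00929), CIN TCP (23 and 8 of 41, 0.00307), circadian clock (29 and 6 of 44, 9.7e-05), abscisic acid (26 and 3 of 59, 0.000287) and seed storage genes (4 and 0 of 5, 0.0145) were higher as well. So were gibberellin (28 and 14 of 54, 0.0489), heat shock (43 and 19 of 86, 0.00218), defence (228 and 82 of 576, 0.000983) and root and nodule genes (13 and 4 of 30, 0.0489), the last with an adjusted p = 0.0984 with an estimated correlation. Ribosomal proteins were lower in the apex in 296 and higher in 10 of 346 (4.11e-30), as were photosynthesis genes (83 and 3 of 116, 6.44e-17) and secondary wall genes (88 and 37 of 196, 0.00618). An estimated correlation gave camera adjusted p-values of 0.00172 for ribosomal proteins and 0.00344 for photosynthesis genes. Adjusted over the list alone the higher and lower counts were 23 and 1 for organ boundary, 23 and 13 for leaf polarity, 24 and 8 for CIN TCP and 43 and 20 for heat shock. They were 225 and 81 for defence, 11 and 300 for ribosomal proteins and 4 and 83 for photosynthesis, and unchanged for the others. In all 21333 genes differed, 10736 higher and 10597 lower. The balance turned to 9835 and 11732 under quantile normalization and 7483 and 8939 with the stricter filter, and was 12272 and 9333 under TPM rescaling. The authors' deposited table gives 32548 of 50633 genes at q under 0.05, 17041 higher and 15507 lower, and 28145 among the genes tested here. Of the 21287 genes called in both, 21283 had the same direction.

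**Figure D4:**
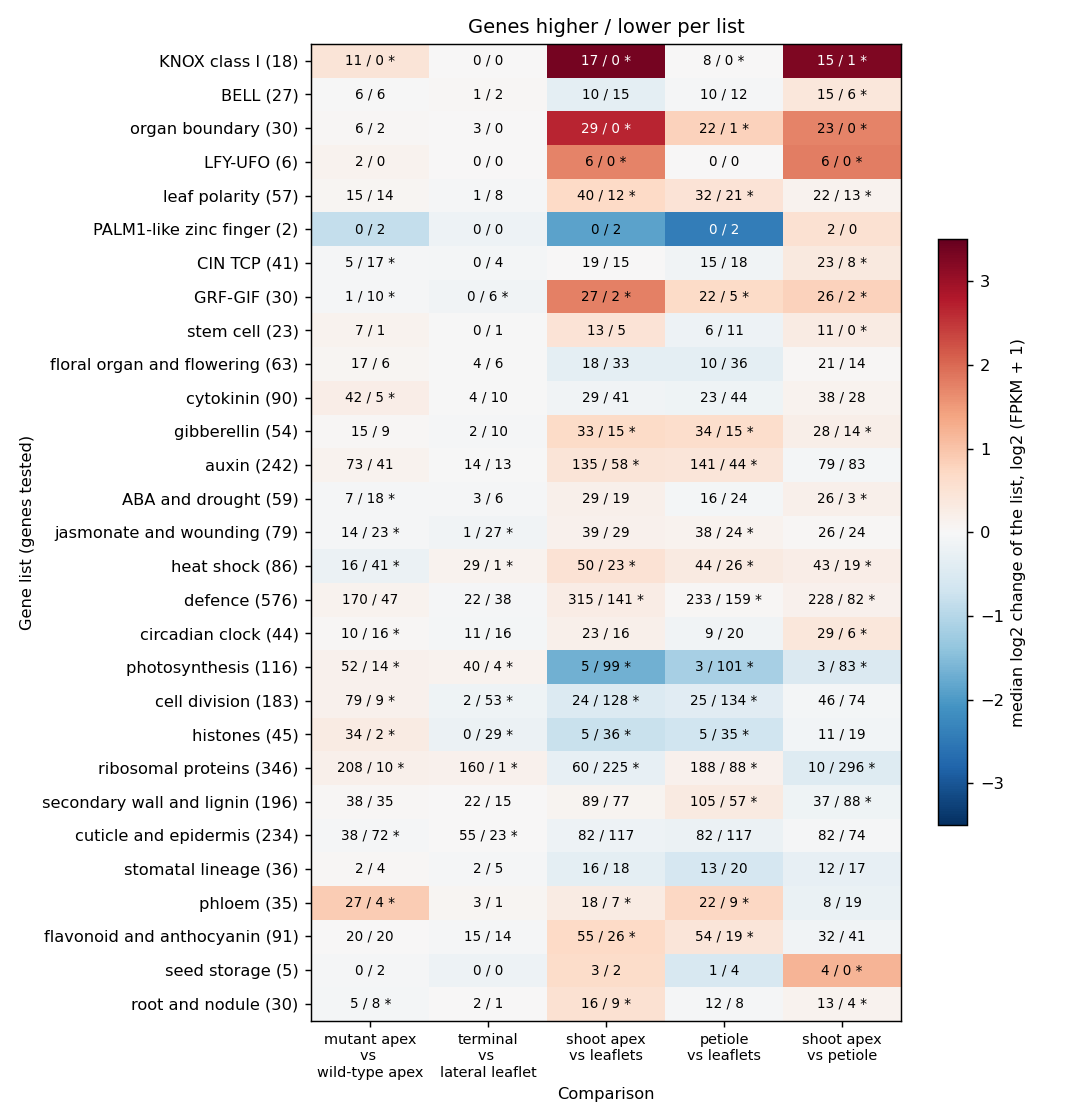
Number of genes higher / lower per list (vertical axis, with the tested genes in brackets) in the 5 comparisons (horizontal axis); colour gives the list's median log2 (FPKM + 1) change and an asterisk a camera adjusted p under 0.05 of 140 tests. KNOX genes are higher in the mutant than in the wild-type apex (11 / 0) and in the apex than in leaflets (17 / 0), and photosynthesis genes are lower in the apex and in the petiole than in leaflets (5 / 99 and 3 / 101).

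The direction of the mutant change was set beside that of the tissue difference between leaflets and apex. Of the 9243 genes higher in the mutant apex, 67.7% were also higher in leaflets than in the wild-type apex, and of the 4633 genes lower in the mutant 74.3% were also lower in leaflets, against 55% higher and 45% lower among all tested genes. Both comparisons share the wild-type apex libraries, and in 100 simulations of unchanged groups against shared controls 69.6% of the genes higher in 1 contrast were higher in the other. Calls higher in both numbered 5464, against 4095 for independent lists, and calls lower in both 3192, against 1634. The covariance of the log2 changes was 0.0868, against 0.00775 in the simulations, and the correlation across genes was 0.226, against 0.577. The simulated groups hold noise alone and no tissue difference, so their share and correlation are not the values to be met by these genes. The wild-type apex libraries were not split between the contrasts, so part of the excess may come from the shared libraries. Against the petiole, which shares no library with the mutant comparison, 56.9% of the genes higher in the mutant were higher in leaflets, against 57.9% of all genes. Of the genes lower in the mutant, 57.3% were lower in leaflets than in the petiole, against 42% of all genes.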

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

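Alternatives fixed before the data were examined were run except those that need read counts (other size factors, other count tests and a second unit), which were not run because the file holds FPKM only. TPM rescaling, the fits without the genes of the chromosome segments or with 1 gene per repeated entry, and the TCP products taken alone were chosen after the data were seen. Asking for at least 2-fold changed the counts most. It left 671 genes for the mutant against the wild-type apex, 246 for terminal against lateral leaflets, 9217 for apex against leaflets, 6713 for petiole against leaflets and 2370 for apex against petiole. All other counts stayed within 1.5 times. For the mutant they ran from 11255 with the stricter filter to 13812 without a filter, and from 11761 to 12283 with single libraries left out.

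With the replicate block 13529 genes were called for the mutant and 4799 for the leaflets. Deviations of libraries with the same replicate number correlated at -0.055 to 0.05 over 30 pairs, and 2 of 15 libraries correlated best with their own number, so the numbers do not pair libraries. The block changed 2 list calls: phloem between leaflets (adjusted p = 0.0496) was gained and root and nodule between apex and petiole (0.0524) was lost.

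Of 140 list tests 73 (52.14%) passed in camera, 68 with an estimated correlation, 69 under quantile normalization and 71 under TPM rescaling. In fry 87.86% passed. In 8 lists that camera did not call, fry called the opposite direction to that of camera. These were organ boundary (0.00189) and gibberellin (0.00232) in the mutant, floral genes between leaflets (0.0188), BELL (2.65e-10) and CIN TCP (5.75e-06) between apex and leaflets, BELL (0.000155) and stem cell genes (2.32e-08) between petiole and leaflets, and the stomatal lineage (1.16e-06) between apex and petiole. The cause was not tested. TPM rescaling lost KNOX between petiole and leaflets (0.0519) and gibberellin (0.0839) and root and nodule (0.0663) between apex and petiole, and gained organ boundary between leaflets (0.0223).

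The share of genes higher in the mutant that were also higher in leaflets than apex was 67.69%. It was 56.89% with leaflets against petiole, 62.17% under quantile normalization, 64.25% under TPM rescaling and 67.87% to 68.49% with single libraries left out. Among the genes of the fixed rule the call of arahy.LJYJ4M.1 between leaflets was lost without replicate 2 of the lateral leaflet (limma adjusted p = 0.0578). None of the rule's genes changed sign with a call.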

Other observations

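The YABBY genes, abaxial regulators of lateral organs, were examined after their values were seen. Of 13 tested in the mutant apex, 8 were lower, 0 higher and 5 not called, within a leaf polarity list that did not pass camera (15 higher and 14 lower of 57, adjusted p = 0.348). In the mutant apex the YABBY5-like gene arahy.FNKT0B.1 had a log2 change of -1.02 (limma adjusted p = 7.62e-07), and arahy.GE3GK9.1 (YABBY 1) fell from 41.9 ± 0.881 to 27.1 ± 1.85 FPKM (n = 3 each). The gene arahy.BZ1GLD.1 (YABBY 4) was not called (log2 change -0.06, adjusted p = 0.65). The clock gene arahy.9UXU7A.1 (REVEILLE 7) had a log2 change of -1.79 in the mutant apex and 1.55 between terminal and lateral leaflets.

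The tests on the 3 patterns below were chosen only after the results were seen. The tests of group splits were chosen before.

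The loss of chromosome 5 genes and rise of chromosome 17 genes in the mutant apex was weighed against an exchange of reads between homeologous copies. The 30 matched copies on chromosome 15 had a median mutant to wild-type ratio of 1.016, where 1.995 would follow, and the 28 matched copies on chromosome 7 one of 1.043, where 0 would follow, which excludes this. For sequence differences scattered over the genome, runs should score within the range of permuted gene orders. The best runs scored 146.3 on chromosome 5 and 44.24 on chromosome 17, against at most 5.412 and 3.487 in permuted orders searched the same way. The segments were selected by these same scores, so this is no separate test of that explanation. A change in gene dosage may account for the pattern: the chromosome 17 segment had a median fold of 2.015, near the 2 of a doubled copy number, and the chromosome 5 segment a median of 0.5% of wild type, although 12 of 66 genes there kept over 20%. No DNA was analysed here, so a stretch of differing sequence on chromosome 5, and whether the segments belong to the mutation or to the plants' background, stay open.

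The rise of KNOX and fall of TCP genes in the mutant apex could come from another mix of tissues in the sample. For a larger share of meristem, the 249 other apex-enriched genes had a median log2 change of -0.19 (SD 0.77 over genes), where at least 0.32 was needed. Of these genes 113 were lower and 43 higher, and the upper quartile of their changes was 0.06. For a smaller share of leaf tissue, the 543 leaflet-enriched genes had a median of 0.01 (SD 0.42), where -0.48 or less was needed, which argues against it by more than their spread. In the 85 of them at 5 FPKM or more in the apex the median was 0.1, with a lower quartile of -0.19 and an SD of 0.65. The needed fall lies within that SD, which is a spread over genes and not an error of the median, so it was not taken as excluded. A different mix of tissues and an effect of the genotype both stay open.

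The LHY differences may reflect harvest at another time of day, as LHY peaks near dawn and GIGANTEA, most APRR and ADAGIO 3 genes later. Between terminal and lateral leaflets the 5 LHY genes had a median log2 change of 2.43 and the 15 later genes one of -0.31 (10 lower, 0 higher), the opposite signs that a shift in phase would give. In the mutant apex the medians were -1.54 and 0.17 (9 of the 15 later genes higher, 2 lower), also of opposite signs. The latter median was below the rise asked for, so it is too small to decide. The 15 genes include the APRR2 genes, with log2 changes of -0.09, 0.04 and 0.05 in the mutant, none called, which pull this median down. The 15 genes leave out the GIGANTEA-like gene arahy.AF3FG0.1 of the chromosome 5 segment (-3.83). The median therefore depends on the members taken, and could move either way. The labels used here give no harvest hour, so harvest time and a difference of tissue or genotype stay open.

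Libraries were regrouped in every possible way to ask how often a random grouping yields as many called genes. Between the apex and the leaflets only the real grouping, 1 of 84, did so (29815 genes, at most 170 otherwise). Between petiole and leaflets it was likewise 1 of 84 (27599, at most 257), and both shares are under 0.05. With 10 groupings the splits are too few for a share under 0.05. There it was 1 of 10 for the mutant (12096, at most 1 otherwise), 1 of 10 for the leaflets (3944, at most 4) and 1 of 10 for apex against petiole (20076, at most 1).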
